A study of Cucumis sativus var. sativus with 11 samples.

How the data were processed

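RNA-seq libraries of 11 cucumber (Cucumis sativus) ovaries were analysed from the processed tables. Per the labels, the ovaries came from the line Elem Female, and each library was made from an individual ovary. Groups were taken from the labels: anthesis (n = 3), pollinated (n = 3) and unpollinated (n = 3) ovaries at 1 day after anthesis, and ovaries pollinated in the presence of older fruits, called inhibited (n = 2). Replicate numbers only name the libraries, since no label pairs them across groups. Whether the ovaries came from separate plants is not stated, so p-values measure the spread between individual ovaries. Within groups no library pair was a duplicate: the chi-square statistic per gene, over genes with at least 20 reads in a pair, was 10.05 or more. It was highest for the inhibited pair, at 51.3, against at most 34.9 for the other pairs. By Pearson correlation of log2 levels, unpollinated replicates 1 and 3 were the least alike (0.975), and the inhibited pair had 0.980. Pairs across groups were not compared in this way.

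The deposited table of raw counts holds whole-number read counts for 23248 genes, and 1330 of these had 0 reads in all libraries. The submitters' processing notes name STAR 2.5.0a, HTSeq 0.6.1p1 and DESeq2 without a version; they give no role for each. The genome build and the annotation are not given in the sources used here. Another 5 lines of each table name no gene and were left out of library sizes and tests: they hold reads that htseq-count assigned to no single gene. Their share was 10.8 to 24.8% of a library's reads, of which reads that overlapped more than 1 gene made up 0.61 to 0.76% of the library. Whether the counting used strand is not given, so genes that overlap on opposite strands, or near-identical copies, may share reads. The second deposited table holds a normalized signal: in every library its values equal the counts divided by 1 factor (largest relative difference 5.1e-10). These factors equal median-of-ratios size factors recomputed with the lines that name no gene included (largest relative difference 1.9e-11; without them 2.4e-05). The raw counts were used for the main tests.

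Genes were filtered with filterByExpr of edgeR 4.0.16 by group, which left 18679 genes. TMM factors were used, and 1 quasi-likelihood model with a mean per group was fitted to all 11 libraries (glmQLFit, glmQLFTest; R 4.3.3). All groups thus share the estimate of the spread, which matters for the inhibited group with n = 2. The common biological coefficient of variation was 12.3%. In all, 6 contrasts were tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM values on TMM-adjusted library sizes. Log2 CPM used a prior count of 2 for principal components, gene groups, distances and the shared response. The median log2 fold change over all genes lay between -0.007 and 0.013 in all 6 contrasts.

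The test, the samples, the alternatives and the rule for naming genes were fixed before the data were examined. The rule had a clause for identifiers without names: in each of the 3 comparisons among the groups taken after 1 day, the 2 genes per direction with the largest log2 fold change among called genes whose groups did not overlap in log2 CPM and whose higher group had a mean of at least 5 CPM. This clause applied, because 0 of the gene identifiers matched the table of 23999 genes of the assembly Cucumber_9930_V3. For the same reason the 33 gene lists fixed beforehand could not be tested. The groups of genes that changed 2-fold or more since anthesis, and the count of genes apart in inhibited ovaries, were defined after the data were seen.

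Pollinated and inhibited ovaries were both compared with the same unpollinated libraries, which raises correlations and overlaps by chance. Unchanged groups were therefore simulated 20 times from the unpollinated means with the fitted dispersions, and the controls were also divided so that the 2 comparisons had no library in common. The part of the pollination response seen in inhibited ovaries is the covariance of the log2 differences less the variance of the control mean, divided by the variance of the pollination response less its replicate variance. Its standard error is a jackknife over 8 libraries. For genes with few reads in a group, ratios of CPM are given with exact conditional binomial 95% intervals. These intervals cover counting error only, since reads were summed over the libraries of a group, which leaves out the spread between ovaries. Reads were also amplified and carry no molecular identifiers in the labels.

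The pipeline was tested on simulated data. Counts were drawn for the real genes, with 200 of them changed. For pollinated against unpollinated ovaries (18518 genes in the fit), 90% of genes changed 4-fold, 76% of those changed 2-fold and 38.8% of those changed 1.5-fold were recovered, but 4.17% of those changed 1.25-fold, with 9 false calls. For inhibited against pollinated ovaries (18503 genes), the shares were 80%, 68%, 22.4% and 10.4%, with 10 false calls. True recoveries at these folds were 45, 38, 19 and 2 genes in the first comparison and 40, 34, 11 and 5 in the second. Far fewer genes were changed here than were called in the real data, so the shares need not carry over. The median size of a called log2 fold change was 0.495 and 0.625 in these comparisons. The part of the response was checked apart from the counts, on normally distributed values with equal noise in every gene and library. A simulated part of 0.5 was recovered as 0.501, which checks the formula alone and not its spread in these data.

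Alternatives were DESeq2 size factors in the edgeR model, no filter on low counts, DESeq2 1.42.0 with its own size factors and filter, limma-trend (limma 3.58.1) on log2 of the deposited normalized signal plus 1, a fit of only the groups compared, and omission of each replicate in turn. After the data were seen, 3 more were added: the share of unassigned reads as a covariate, the second index sequence of the library as a term, and omission of the 4 libraries whose unassigned share exceeded that of every anthesis library. The second index parts the libraries into anthesis, pollinated and unpollinated replicate 1 on one side and unpollinated replicates 2 and 3 and the inhibited libraries on the other. Anthesis replicate 3 was sequenced on lane 2 and all other libraries on lane 3.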

Results

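RNA was sequenced from 11 individual cucumber ovaries of Elem Female, a gynoecious line that sets fruit only after pollination. Libraries fell into 4 groups. Anthesis ovaries were taken on the day the flower opened (n = 3). The other groups were taken 1 day later and were pollinated ovaries (n = 3), unpollinated ovaries (n = 3) and inhibited ovaries, which were pollinated while older fruits were already on the plant (n = 2). Each library held between 18158218 and 26456643 reads assigned to genes, and between 19849 and 20447 genes had at least 1 read. The gene with the most reads took 0.346 to 0.535% of the gene reads in 7 libraries. It took 1.83% in pollinated replicate 1, 1.46% in pollinated replicate 3, 1.05% in unpollinated replicate 3 and 2.59% in inhibited replicate 2, the same 4 libraries that had a raised share of reads assigned to no single gene (16.8 to 24.8%, against 10.8 to 13.3% in the others). Genes are given by their identifiers, because the files do not pair them with names and 0 of the identifiers matched the reference gene table. What each gene encodes is therefore not stated.

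Libraries of a group lay together along the main axes of variation, with 1 exception. The first principal component (32.7% of the variance) placed pollinated ovaries between 40.1 and 47.2 and anthesis ovaries between -43.8 and -22.9. Unpollinated replicates 1 and 2 lay at -32.0 and -23.8 on this axis, while unpollinated replicate 3 lay at 19.9. The second component (24.0%) separated all 3 unpollinated libraries, at -48.6 to -30.9, from the other 8 libraries, which lay above -3.5. Inhibited ovaries stood apart on the third component (13.5%), at -45.0 and -41.0, with every other library above 0.

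**Figure D1:**
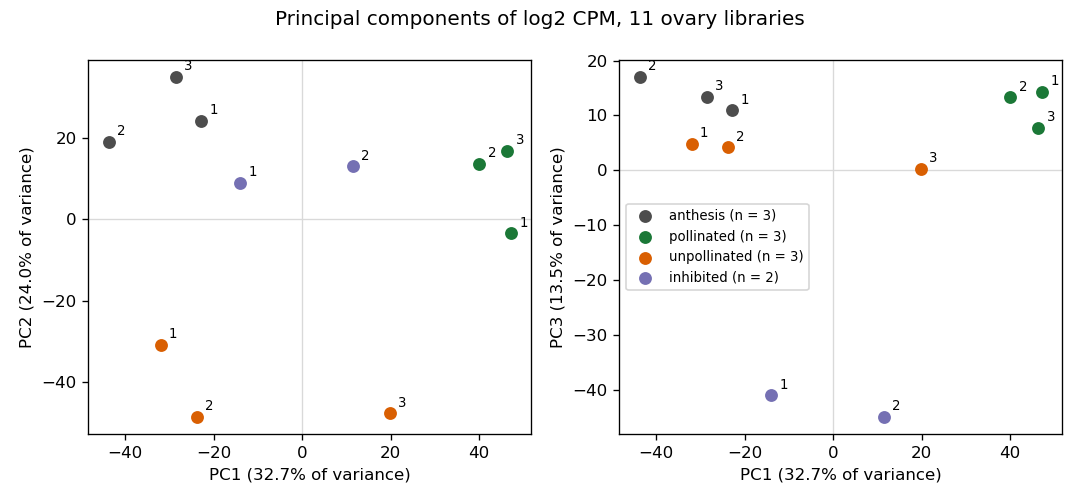
Principal components of the log2 CPM values of 11 libraries; each point is 1 library, numbered by replicate, and axes give the component score with its share of the variance. Pollinated libraries lie between 40.1 and 47.2 on the first component, unpollinated libraries between -48.6 and -30.9 on the second, and inhibited libraries at -45.0 and -41.0 on the third.

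The first comparison asked how an ovary that received pollen differed after 1 day from an ovary of the same age that did not. Pollinated ovaries had 2799 genes at higher and 2852 at lower levels than unpollinated ovaries, 30.2% of the 18679 genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At 2-fold or more, 652 genes were lower and 293 higher (571 and 159 with the second index as a term). Csa2G379350 was 22.3-fold higher with pollination (log2 fold change 4.48 ± 0.37 SE, edgeR adjusted p = 1.36e-05). Its level was 12.7 ± 2.38 CPM in pollinated ovaries (SD, n = 3) and 10.2 ± 1.72 CPM at anthesis (SD, n = 3), against 0.580 ± 0.531 CPM without pollination (SD, n = 3). Csa5G644580 showed the same order, with 14.1 ± 2.18 CPM in pollinated, 9.53 ± 1.23 CPM in anthesis and 0.889 ± 0.633 CPM in unpollinated ovaries (SD, n = 3 each); its log2 fold change was 4.01 ± 0.35 SE (edgeR adjusted p = 1.83e-05). Among the genes open to the naming rule, Csa3G736970 had the lowest log2 fold change with pollination, at 0.145 ± 0.130 CPM against 16.0 ± 12.6 CPM without it (SD, n = 3 each). Its log2 fold change was -6.74 ± 0.72 SE (edgeR adjusted p = 6.7e-05), and at anthesis it lay at 0.607 ± 0.225 CPM (SD, n = 3). Csa6G085120 fell from 4.92 ± 1.28 CPM at anthesis to 0.109 ± 0.094 CPM after pollination, and stood at 9.69 ± 2.26 CPM without it (SD, n = 3 each; log2 fold change between the latter groups -6.49 ± 0.61 SE, edgeR adjusted p = 3.07e-05). The last 2 genes had few reads in pollinated ovaries, 10 and 7 over the 3 libraries, and the exact 95% counting intervals of their ratios ran from 61.6 to 237.7 and from 45.6 to 236.0. Without unpollinated replicate 1 the log2 fold changes of Csa2G379350 and Csa5G644580 were 5.51 and 4.73, and with the second index as a term 3.41 and 3.13. That of Csa3G736970 was -7.785 without pollinated replicate 2, -5.89 without unpollinated replicate 2 and -5.41 with the index term, and -5.97 without the 4 libraries with a raised share of unassigned reads. For Csa6G085120 it was -5.84 without pollinated replicate 3. The count of 5651 fell to 3365 without unpollinated replicate 2, to 3659 without pollinated replicate 2 and to 3630 without pollinated replicate 3. With the second index sequence of the libraries as a term it was 1883, and without the 4 libraries with a raised share of unassigned reads it was 3436.

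**Figure D2:**
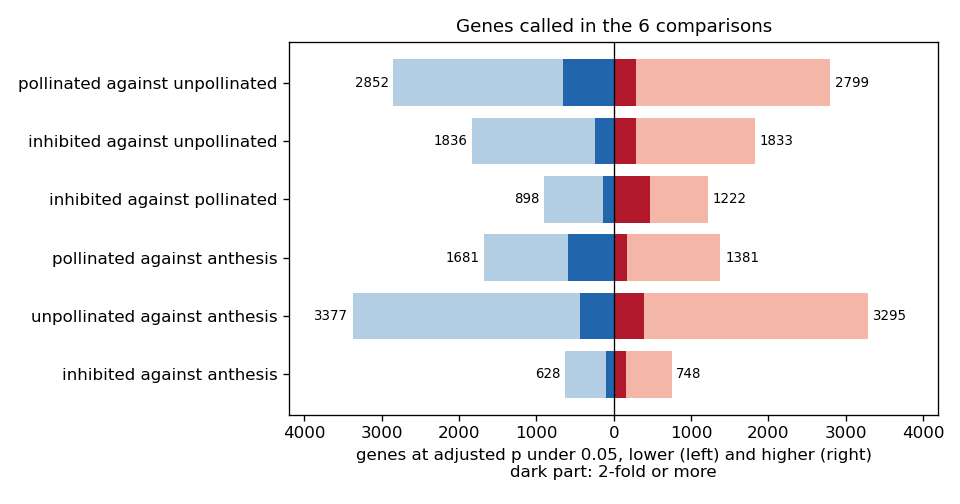
Number of genes called in each of the 6 comparisons (adjusted p under 0.05); bars to the left of 0 count lower genes, bars to the right higher genes, and the dark part counts those that differed 2-fold or more. Unpollinated ovaries against anthesis gave the longest bars, 3295 higher and 3377 lower, and inhibited ovaries against anthesis the shortest, 748 and 628.

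Inhibited ovaries were then compared with unpollinated ovaries, from which they differ in both pollination and the presence of older fruits. No unpollinated group with older fruits was analysed here. They had 1833 genes at higher and 1836 at lower levels, of which 291 and 241 differed 2-fold or more. Csa4G267480 had 1 read over the 3 unpollinated libraries and 1 read over the 3 anthesis libraries, and 82 and 188 reads in the inhibited libraries. Its level was 6.12 ± 2.10 CPM in inhibited (SD, n = 2) and 1.04 ± 0.65 CPM in pollinated ovaries (SD, n = 3). The ratio of inhibited to unpollinated ovaries was 441.1, with an exact 95% counting interval of 78.5 to 17490 (edgeR adjusted p = 8.19e-05). Csa5G054060 showed the same order, with 3 reads over the unpollinated libraries, 5.15 ± 2.49 CPM in inhibited ovaries (SD, n = 2) and a ratio of 125.8 (42.5 to 614.4; edgeR adjusted p = 0.001). Csa3G778180 was lower in inhibited ovaries, at 4.72 ± 2.90 CPM (SD, n = 2) against 58.8 ± 35.8 CPM in unpollinated ones (SD, n = 3; log2 fold change -3.69 ± 0.62 SE, edgeR adjusted p = 0.00216). Csa1G611290 stood at 2.18 ± 0.92 CPM in inhibited ovaries (SD, n = 2), below unpollinated (19.1 ± 5.39 CPM), pollinated (17.0 ± 6.77 CPM) and anthesis ovaries (8.35 ± 1.30 CPM; SD, n = 3 each). Its log2 fold change against unpollinated ovaries was -3.09 ± 0.37 SE (edgeR adjusted p = 0.000284). The log2 fold change of Csa3G778180 was -3.07 without unpollinated replicate 3 and -4.46 without inhibited replicate 2; that of Csa1G611290 was -2.502 without the 4 libraries with a raised unassigned share. The count of 3669 fell to 1785 without unpollinated replicate 2, to 1955 without inhibited replicate 2 and to 1858 without the 4 libraries with a raised unassigned share. It was 3337 with the second index as a term.

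Inhibited and pollinated ovaries had both received pollen and differed in the presence of older fruits. They also differed in the second index sequence, of which all pollinated libraries carried 1 form and both inhibited libraries the other. Inhibited ovaries had 1222 genes at higher and 898 at lower levels. These counts were 787 and 686 without pollinated replicate 3, and 923 and 524 in a fit of only these 2 groups. Large differences were mostly in 1 direction, with 470 genes at least 2-fold higher and 133 at least 2-fold lower (136 and 66 without inhibited replicate 1, 340 and 72 with the second index as a term). Csa3G736970 was 46.7-fold higher in inhibited ovaries, at 6.99 ± 2.46 CPM (SD, n = 2; log2 fold change 5.55 ± 0.77 SE, edgeR adjusted p = 0.00107). The exact 95% counting interval of its ratio was 26.9 to 105.4, and its log2 fold change was 6.595 without pollinated replicate 2, 3.85 with the second index as a term and 4.90 without the 4 libraries with a raised unassigned share. Csa4G001850 stood at 10.8 ± 1.22 CPM in inhibited ovaries (SD, n = 2) and at 19.3 ± 5.88 CPM at anthesis (SD, n = 3). Unpollinated replicates 1 and 2 had 16.5 and 7.45 CPM. The gene was not called between inhibited ovaries and anthesis (edgeR adjusted p = 0.589) or unpollinated ovaries (edgeR adjusted p = 0.776). It had 0 reads in pollinated replicates 1 and 2 and in unpollinated replicate 3, and 0.925 CPM in pollinated replicate 3. Its log2 fold change of 4.95 ± 1.25 SE (edgeR adjusted p = 0.024) was no longer called with DESeq2 or without any 1 of pollinated replicates 1 and 2 and inhibited replicates 1 and 2; without pollinated replicate 3 its pollinated libraries were all at 0 reads. Csa3G218170 was at 101 ± 31.2 CPM in pollinated (SD, n = 3) and 64.1 ± 26.9 CPM in unpollinated ovaries (SD, n = 3), but at 11.6 ± 2.46 CPM in inhibited ovaries (SD, n = 2), close to its 11.4 ± 2.61 CPM at anthesis (SD, n = 3). The log2 fold change of inhibited against pollinated ovaries was -3.12 ± 0.38 SE (edgeR adjusted p = 0.000428), and -4.155 with the second index as a term. Csa1G611290 was also lower in this comparison (log2 fold change -2.91 ± 0.37 SE, edgeR adjusted p = 0.000589; -2.12 without the 4 libraries). The count of 2120 fell to 522 without inhibited replicate 1 and was 1796 without inhibited replicate 2. The count was 569 with the second index as a term, where 73.5% of calls were higher in place of 57.6%, and 904 without the 4 libraries with a raised unassigned share.

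**Figure D3:**
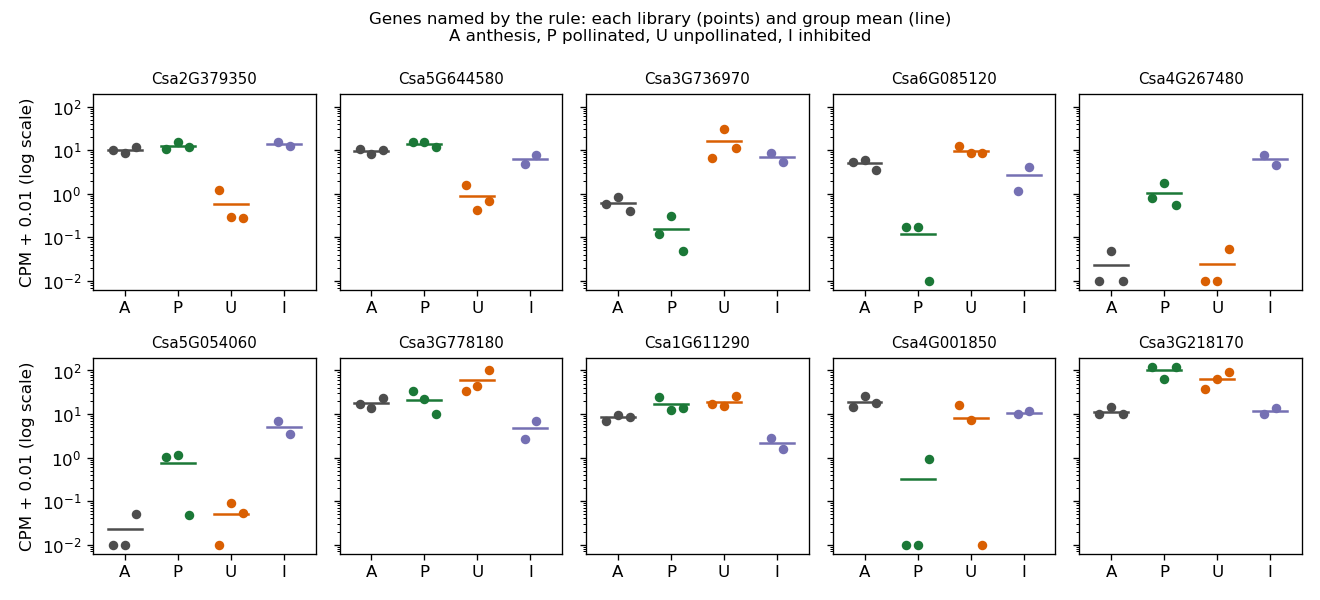
Level of the 10 genes named by the rule in each library (points) and the group mean (lines), as CPM plus 0.01 on a log axis, for anthesis (A), pollinated (P), unpollinated (U) and inhibited ovaries (I). Csa4G267480 and Csa5G054060 have mean levels of 6.12 and 5.15 CPM in inhibited ovaries and at most 1 or 2 reads in any anthesis or unpollinated library.

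Inhibited ovaries also differed from all the other groups at once. Levels of 156 genes were higher and of 91 genes lower in inhibited ovaries than in each of the anthesis, pollinated and unpollinated groups. When the inhibited libraries were simulated from the pollinated means, at most 1 gene in each direction met this condition in 20 simulations, as error control alone would give where no inhibited gene differs from pollinated ovaries. These counts rested on inhibited replicate 1 more than on replicate 2: without replicate 1 they were 38 and 21. They also fell to 80 and 38 without anthesis replicate 1 and to 95 and 34 without anthesis replicate 3. The lower count was 50 without unpollinated replicate 2, 49 with only the groups compared in each fit, and 169 with DESeq2. They were 11 and 0 with the second index as a term (233 lower at an unadjusted p under 0.05 in all 3 edgeR tests), and without the 4 libraries with a raised unassigned share the higher count was 64.

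Each group was next compared with anthesis, to follow the change over 1 day. Unpollinated ovaries differed in the largest number of genes, with 3295 higher and 3377 lower, of which 392 and 431 differed 2-fold or more. Pollinated ovaries differed in 3062 genes, and among those at 2-fold or more, 590 fell and 168 rose. Inhibited ovaries differed in 1376 genes (748 higher and 628 lower, of which 155 and 94 at 2-fold or more). Fewer libraries in that group (n = 2 against 3) also lower its number of calls. Csa3G218170 rose in both other groups, by a log2 fold change of 3.15 ± 0.32 SE with pollination (edgeR adjusted p = 0.000179), to the levels given above. In inhibited ovaries its log2 fold change was 0.02 ± 0.36 SE (edgeR adjusted p = 0.976). Csa2G379350 had a log2 fold change of -4.16 ± 0.37 SE without pollination (edgeR adjusted p = 7.02e-05). The root mean square log2 difference from anthesis over all genes, after removal of the replicate variance, was 0.536 for pollinated, 0.467 for unpollinated and 0.396 for inhibited ovaries. When 1 library was left out, these ran from 0.511 to 0.557, from 0.427 to 0.519 and from 0.384 to 0.484. The range of unpollinated ovaries thus overlaps those of pollinated and of inhibited ovaries, and its place in the order is not settled.

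The numbers of calls against anthesis depended on single libraries. For pollinated ovaries the count was 1997 without anthesis replicate 1, 1509 without anthesis replicate 3, and 2022, 1965 and 1775 without pollinated replicates 1, 2 and 3. For inhibited ovaries it was 559 and 345 without anthesis replicates 1 and 3, and 414 and 861 without inhibited replicates 1 and 2. Of the genes that differed 2-fold or more, the 168 that rose with pollination became 87 without anthesis replicate 3 and 110 without pollinated replicate 1, 94 with the unassigned share as a covariate and 65 without the 4 libraries in which it was raised. The 155 genes higher in inhibited ovaries became 88 without anthesis replicate 3 and 72 without inhibited replicate 1. The 94 lower genes became 39 and 33 without anthesis replicates 2 and 3, and 24 and 45 without inhibited replicates 1 and 2. With the covariate the 94 became 37, with DESeq2 151, and with the second index as a term the 155 and 94 became 15 and 2. Anthesis replicate 3 was the only library sequenced on lane 2, so its omission also gives the comparison within lane 3. With the second index as a term, the counts were 3131 for pollinated, 1578 for unpollinated and 17 for inhibited ovaries. With the share of unassigned reads as a covariate they were 1046, 6573 and 669.

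Genes that changed 2-fold or more since anthesis were followed as groups through every library. Of these, 156 fell both with and without pollination and 50 rose in both, where independent lists would share 13.6 and 3.53. Another 12 fell with pollination and rose without it and 3 did the reverse, against 12.4 and 3.88. Each choice used the same anthesis libraries, which favours an overlap in the same direction. Of the genes that fell with pollination, 214 were also called lower and 22 higher in unpollinated ovaries than at anthesis. The 590 genes that fell with pollination lay at medians of -1.79 to -1.73 (log2 against the anthesis mean) in the 3 pollinated libraries. In unpollinated ovaries the medians were -0.26 and -0.66 in replicates 1 and 2, but -1.47 in replicate 3. Inhibited ovaries lay at -0.49 and -0.71, above every pollinated library. Of the 590 genes, 261 were called higher and 0 lower in inhibited than in pollinated ovaries, with 329 not called (edgeR; also 0 lower at an unadjusted p under 0.05 and with DESeq2). At 1 day, 334 of the 590 were lower in pollinated than in unpollinated ovaries and 3 were higher. These genes were chosen as low in the same pollinated libraries, which favours both directions. Between inhibited and unpollinated ovaries, which took no part in the choice, 24 of the 590 were higher and 18 lower, with 548 not called. Over all genes tested, 19.6% were called in that comparison. Unpollinated replicate 3 lay well below replicates 1 and 2 on the 590 genes, and such scatter makes a call less likely. The few calls therefore do not show that inhibited and unpollinated ovaries were alike on them. The 168 genes that rose with pollination had medians of 1.43 to 1.68 in pollinated, 0.44 to 0.94 in unpollinated and 0.62 to 0.82 in inhibited libraries. The count of 261 fell to 80 without inhibited replicate 1, to 172 without pollinated replicate 1 and to 170 without pollinated replicate 2, and the count of 334 to 205 to 220 without pollinated replicate 2 or 3 or unpollinated replicate 1 or 2. With the unassigned share as a covariate the 334 became 156 and the 590 became 296, and 370 without the 4 libraries in which it was raised.

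The genes that changed without pollination were followed in the same way. In every set, the group used to choose the genes lay furthest from the anthesis mean, as the choice favours. The 392 genes that rose in unpollinated ovaries had medians of 1.26 to 1.44 there, against 0.13 to 0.70 in pollinated and 0.48 and 0.53 in inhibited libraries. Of these genes, 267 were lower in pollinated and 199 lower in inhibited than in unpollinated ovaries, while 2 and 1 were higher. The choice of genes high in these unpollinated libraries favours that direction. The 431 genes that fell without pollination had medians of -1.61 to -1.04 in unpollinated, -0.77 to -0.61 in pollinated and -0.67 and -0.66 in inhibited libraries. In this group 183 genes were higher in pollinated and 154 higher in inhibited than in unpollinated ovaries, with 37 and 1 lower, a direction that the choice of genes likewise favours. The count of 199 was 116 without unpollinated replicate 2 and 132 without inhibited replicate 2. Adding the second index as a term, which leaves unpollinated replicate 1 alone to be set against anthesis, the 392 and 431 genes became 205 and 119, and the 267 and 199 became 120 and 119.

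**Figure D4:**
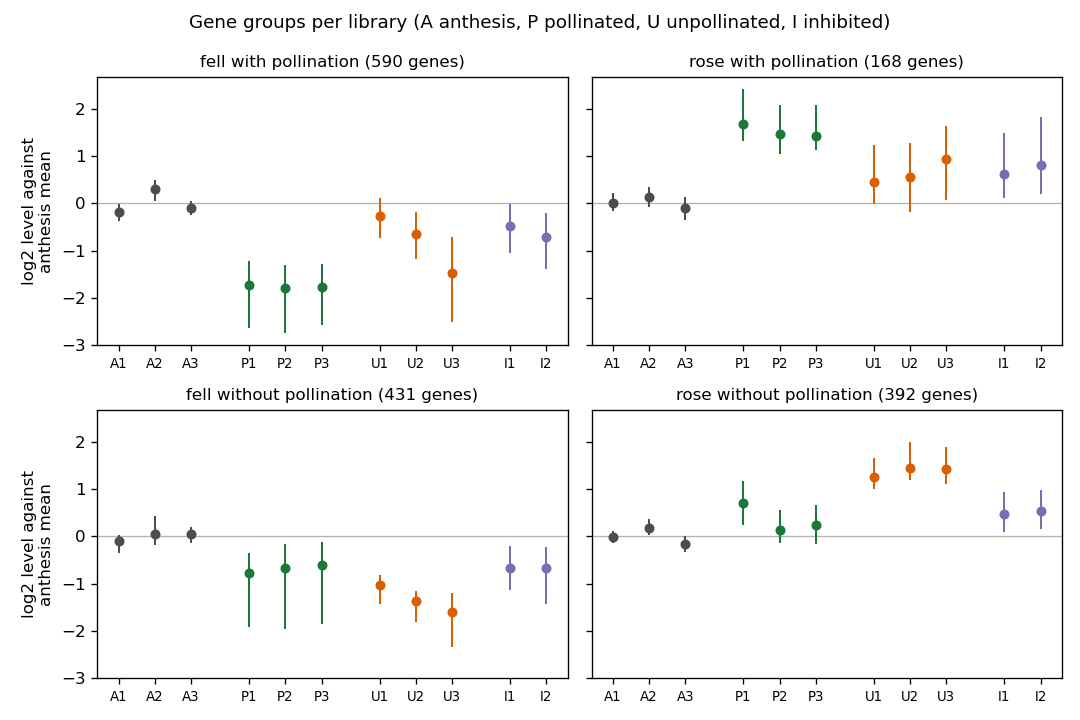
Median log2 level against the anthesis mean (points) with the middle 50% of genes (bars) in each library, for genes that changed 2-fold or more since anthesis with pollination (590 fell, 168 rose) or without it (431 fell, 392 rose). On the 590 genes, pollinated libraries lie at -1.79 to -1.73, inhibited libraries at -0.49 and -0.71, and unpollinated replicate 3 at -1.47.

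The calls of pollinated and of unpollinated ovaries against anthesis were then compared with each other. Levels of 676 genes were higher and of 728 lower than at anthesis in both groups, where independent lists of these sizes would share 243.6 and 303.9. Opposite calls were fewer, 91 genes lower with pollination and higher without it and 69 the reverse, against 296.5 and 249.7 for independent lists. Both comparisons used the same anthesis libraries, which can raise the overlap by chance. Simulated unchanged groups shared 0 calls (edgeR), which does not measure this, because groups without changes give almost no calls. Part of the excess over independent lists may come from the shared libraries. Among single omissions, that of anthesis replicate 3 lowered the counts of 676 and 728 most, to 216 and 302. Without anthesis replicate 1 they were 412 and 475, without pollinated replicate 1 they were 352 and 430, and without pollinated replicate 3 or unpollinated replicate 2 they lay at 434 to 445 and at 448 to 478. With the unassigned share as a covariate they were 206 and 304, with the second index as a term 186 and 226, and without the 4 libraries with a raised share 87 and 140. The opposite counts lay between 43 and 112 and between 32 and 86 when any 1 library was left out, lowest without anthesis replicates 2 and 1. Over the other alternatives they ran from 34 to 124 and from 18 to 87.

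The last comparison set the pollinated and the inhibited response against unpollinated ovaries side by side. Of the called genes, 1180 were higher and 987 lower in both pollinated and inhibited ovaries, and 48 went opposite ways; independent lists would share 274.7, 280.3 and 555. Simulated unchanged groups shared 0 calls, but groups without changes give almost no calls, so this value does not measure how far the shared controls raise an overlap. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.547 and a Spearman correlation of 0.562. Simulated unchanged groups against the same controls gave 0.445 and 0.407 on average. The covariance was 0.163, against a simulated mean of 0.0268 and a highest value of 0.029. After removal of the variance of the shared controls, the part of the pollination response seen in inhibited ovaries was 0.487. Its jackknife standard error was 0.225. Both responses are measured from unpollinated ovaries, so a change of these since anthesis raises the part as a shift in inhibited ovaries would. Unpollinated ovaries differed from anthesis in 6672 genes, inhibited ovaries (n = 2) in 1376. When the 2 comparisons shared no control library, the covariance averaged 0.124 (0.0454 to 0.170 over the 6 ways of dividing the controls) and the Pearson correlation 0.371 (0.116 to 0.516). Of the 2799 genes higher in pollinated than in unpollinated ovaries, 385 were lower and 65 higher in inhibited than in pollinated ovaries. Of the 2852 lower genes, 729 were higher and 32 lower in inhibited than in pollinated ovaries. Both choices use the pollinated libraries that inhibited ovaries are then set against, which favours the larger count. Without unpollinated replicate 2 the shared calls were 508 and 419 with 16 opposite, and without inhibited replicate 2 they were 566 and 516. Without inhibited replicate 1 the opposite calls were 21, and the 385 and 729 became 132 and 200. Those last counts were 225 and 447 without pollinated replicate 2, and 220 and 444 without pollinated replicate 3. With the second index as a term the shared calls were 354 and 322, the 385 and 729 became 53 and 319, and the correlation was 0.263.

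Depth set which differences could be seen. In the comparison of pollinated with unpollinated ovaries, 11.3% of the 1479 tested genes with a mean under 1 CPM were called, and 42.4% of the 2496 genes at 100 CPM or more. The median standard error of the log2 fold change was 0.596 in the first class and 0.0804 in the second. A gene that was not called is therefore not shown to be unchanged.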

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

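The tests of the raised share of unassigned reads reported here were named before their results were seen, and the covariate itself was chosen after the data were seen. Reads that htseq-count assigned to no single gene lie outside the gene measurements. Their share was 10.8 to 13.3% in anthesis ovaries but 21.1% in pollinated replicate 1, 20.5% in pollinated replicate 3, 16.8% in unpollinated replicate 3 and 24.8% in inhibited replicate 2. In these 4 libraries the gene with the most reads was Csa4G243390, singled out after its values were seen, at 1.05 to 2.59% of the gene reads, against 0.0757 to 0.434% in the other 7 libraries.

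The raised share fell in 3 of the 4 groups, so it did not follow the design alone, but 2 of the 3 pollinated libraries had it. With the share as a covariate, 75.2% of the calls between pollinated and unpollinated ovaries stayed called in the same direction, which argues against the share as the source of most of them. Within groups, 42 of the 18679 genes followed the share at an adjusted p under 0.05 (edgeR). Of the 590 genes that fell with pollination, 0 were among them and 34 had an unadjusted p under 0.05 (edgeR). With so few calls over all genes, 0 of 590 tells little. The 590 were also called with these libraries, and scatter within groups makes a call less likely. How the share acts on the counts therefore stays open. The comparison of pollinated ovaries with anthesis is the least settled, since 32.8% of its calls were kept under the covariate, and there the share and pollination largely coincide. No biological explanation of the share itself was tested.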

How the results depend on the processing

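All 6 counts of called genes stayed within 1.5 times of their value with DESeq2 size factors in edgeR, without the filter on low counts and with limma-trend. DESeq2 raised inhibited against anthesis to 2361 genes, and a fit of only those groups lowered it to 863. Leaving out 1 library gave 3365 to 5880 genes for pollinated against unpollinated, 1785 to 3347 for inhibited against unpollinated, 522 to 1796 for inhibited against pollinated, 1509 to 2162 for pollinated against anthesis, 4564 to 6642 for unpollinated against anthesis and 345 to 959 for inhibited against anthesis. Where an arm was left with 1 library, as inhibited ovaries without a replicate and both pollinated and inhibited ovaries without the 4 libraries named below, it was assumed to vary like the other groups. The following alternatives were chosen after seeing the data. With the second index as a term the counts were 1883 for pollinated against unpollinated, 569 for inhibited against pollinated, 1578 for unpollinated against anthesis and 17 for inhibited against anthesis; by construction this term leaves fewer libraries to carry those comparisons. With the unassigned share as a covariate, pollinated and inhibited against anthesis gave 1046 and 669; the cause was not tested. Without the 4 libraries with a raised share the counts were 3436, 1858 and 904 among the groups taken after 1 day and 790 and 806 for pollinated and inhibited against anthesis, with fewer samples in each. The correlation of the shared response was 0.263 with the index term and 0.371 with no control in common, and 0.409 to 0.633 when a library was left out. Of 136 alternative values for the named genes, 131 kept direction and call, 5 (all of Csa4G001850) lost the call and 0 reversed. Of 619 values for directional counts, counts over several comparisons and the part of the response, 467 stayed within 1.5 times or the jackknife error. No paired analysis was possible because the labels do not pair ovaries across groups. The gene list tests and their alternatives were not run. In 3 comparisons of 3 against 3 libraries, 1 of the 10 splits, the real one, called as many genes as observed (5651, 3062 and 6672); the highest of the other splits called 0 with edgeR (2050, 1038 and 1069 genes at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. Depth limits genes under 1 CPM, where the median standard error was 0.596.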

Other observations

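In this part, the tests of the genes nearly absent without pollen, of the library label, of the unassigned reads in the fallen genes, of the shared controls and of neighbouring identifiers were chosen after the result was seen, that of unassigned reads in place of an earlier test that could not tell; the other tests were named beforehand.

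A small group of genes was read almost only in ovaries that had received pollen. Over the 6 anthesis and unpollinated libraries, 38 genes had at most 3 reads in sum, yet at least 30 reads over the 5 pollinated and inhibited libraries; the reverse condition gave 10 genes. Together they made up 6.90 to 13.2 CPM in pollinated and 69.3 and 45.4 CPM in inhibited ovaries, against 0.138 to 0.392 CPM in the other libraries. The summed level was 5.96 times higher in inhibited than in pollinated ovaries, and 37 of the 38 genes had the higher level there. The minimum of 30 reads is passed most easily by genes high in inhibited ovaries, which favours this direction; when the 30 reads had to lie in the pollinated libraries alone, 6 genes were left, 5 of them higher in inhibited ovaries (median ratio 4.87). Of the 33 that were tested, 22 were called higher in inhibited than in pollinated ovaries and 0 lower (edgeR; also 0 at an unadjusted p under 0.05 and with DESeq2).

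No other of the 462 splits of the 11 libraries into 6 and 5 gave as many such genes: the count of splits was 1, and the highest of the others gave 20 genes, which argues against an arbitrary division of the libraries. A candidate explanation is 1 source of RNA that comes with pollination and is present in a larger proportion in inhibited ovaries. It predicts 1 ratio for all genes, and 18.4% of them (7 of 38) divided their reads between inhibited and pollinated libraries differently from the rest (exact binomial tests, adjusted p under 0.05). These tests cover counting error only and leave out the spread between ovaries. The share also lies between the bounds set for and against the explanation, which therefore stays open. Markers of pollen could not be applied, because the identifiers are not paired with names.

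Unpollinated replicate 3 resembled the pollinated ovaries on the genes that fell with pollination, but less so on the other called genes. On the 426 of those genes called lower in pollinated than in unpollinated replicates 1 and 2, its median position was 0.242, where 0 is the pollinated mean and 1 the mean of the other unpollinated replicates; on the 4513 other called genes it was 0.884, which argues against a wrong label. Replicate 3 lay 1.01 below the other unpollinated replicates in the median log2 level of the 590 fallen genes. The largest such drop of the 3 other libraries with a raised share, all higher than its own, was 0.222 (inhibited replicate 2). That drop compares 1 library with 1 other and has no spread, and the pollinated libraries, low in these genes anyway, tell little. With the share as a covariate the 590 became 296. The amount of unassigned reads therefore stays open. Loss of 1 part of the organ as a unit stays open: 3.73% of the fallen genes were called higher than at anthesis in unpollinated ovaries without replicate 3, but genes chosen as high at anthesis give a low share under any cause. A shared regulation of these genes was not tested and stays open too.

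Inhibited ovaries differed from unpollinated ones in part as pollinated ovaries did. The covariance of both responses, 0.163, lay above the range of 0.0254 to 0.029 from simulated unchanged groups. The simulated noise was drawn for each gene apart, so it leaves out a shift of 1 library on many genes together. With no control library in common the covariance averaged 0.124 (0.0454 to 0.170 over the ways of dividing the controls). Replicate noise in the shared controls therefore does not account for all of the covariance. The covariance was also taken within each index group, with unpollinated replicate 1 for pollinated and replicates 2 and 3 for inhibited ovaries. Divided by the variance of the pollination response over all unpollinated libraries, less replicate variance, it gave a part of 0.386. The bound set against an index batch was a part over 0.3, which this value passes. It does not pass once the jackknife standard error of 0.225 is allowed for, a margin that the bound itself did not include. That error belongs to the estimate from all controls, while here the pollinated side rests on 1 control library. An index batch therefore stays open. Unpollinated ovaries differed from anthesis in 6672 genes, and such a change enters both responses. How much of the part it accounts for was not tested and stays open too. A partial response to pollen under older fruits stays as a hypothesis that rests on 2 inhibited libraries: the part was 0.355 without replicate 2 and 0.620 without replicate 1.

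Genes called between pollinated and unpollinated ovaries often had neighbouring identifiers. Among 18556 genes ordered by the number in the identifier, 20.9% of called genes were followed by one called in the same direction, against 15.2% on average and 17.5% at most in 1000 shuffles within the leading digit and 10 classes of expression. The files do not state what the numbers stand for, and reads shared between similar copies could add to it.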
